A study of Caenorhabditis elegans with 9 samples.

How the data were processed

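Whole animals labelled as synchronised first-stage larvae were measured on 9 expression arrays, 3 each for N2 control, aex-3 SUMO and myo-4 SUMO. Per the labels' protocols, animals were grown on OP50 bacteria and synchronised by bleaching, RNA was isolated with RiboPure, and biotin-labelled cRNA was made from 10 µg of total RNA. The deposited values are linear signal intensity per probe set, made with GCOS, per the submitters' processing notes, which give no version. The 2% trimmed mean of the arrays differed by 0.01%, so the values were taken as already scaled and were used as deposited. Scaling to a common trimmed mean fixes that agreement, so it does not show that the arrays are comparable. No background threshold or detection call is in the deposited table. The array medians were 27.57 to 28.62 in N2 and 23.19 to 25.71 in the transgenic lines. This offset runs along the comparisons with N2 and cannot be told apart from them. The number of arrays limits the precision.

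The table holds 22625 probe sets, of which 77 control probe sets were left out. Values were transformed as log2(signal + 1.623), where 1.623 is the median over arrays of each array's 10th percentile, so changes of dim genes are drawn toward 0. Probe sets above the 40th percentile of their array on at least 3 of the 9 arrays were kept, which left 14204. All 9 arrays entered a limma fit (limma 3.58.1 in R 4.3.3; lmFit, and eBayes with an intensity trend), with 6 residual degrees of freedom and 6.88 prior degrees of freedom. The contrasts were each transgenic line against N2, and myo-4 SUMO against aex-3 SUMO. Tests are two-sided, with Benjamini-Hochberg adjustment over the probe sets kept, per contrast, at a threshold of 0.05. Replicate numbers were not taken as pairs, since the correlations of the replicates' deviations were -0.194 to 0.0295. The hybridisation spike-ins did vary with the replicate number (86.4% of their variance between arrays). A fit with the replicate number as a block is among the alternatives.

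Probe sets were named through the deposited probe table's gene identifiers and a table of genes on assembly WBcel235, used for names, chromosomes and neighbours only. Of 22548 probe sets, 20810 had 1 gene, 843 several and 895 no name; among those kept the numbers were 13447, 475 and 282. Probe sets with several genes stayed in the counts but are not named and enter no list. For lists, 1 probe set per gene was used, that with the highest mean signal over all arrays, which gave 10788 genes. The probe table names no probe set for ubc-9, uba-2 or mms-21 of the SUMO pathway. Neither the construct's nor the probes' sequences were at hand, so whether the smo-1 probe set detects transcripts of the transgene is unknown.

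Lists of genes for pathways and cell types, 22 in all, were fixed before the data were examined, as were the tests of the comparisons and lists, most alternatives and the rule for named genes. Among the lists, those of adult gonad, oocyte, sperm and yolk and of the embryo serve as checks of stage. Some genes stand in more than one list. Lists and the 147 classes of gene symbols with at least 8 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with the rotation test fry, which asks whether a list moves one way on its own. The p-values were adjusted over lists or classes per contrast. Counts of list members use the adjustment over all probe sets kept; those adjusted over the list alone are given beside them. Calls were also compared between chromosomes by Fisher's exact test, and called neighbours were counted against 10000 random draws.

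Named genes follow a rule. In each comparison with N2 these are the 10 highest and the 10 lowest log2 fold changes among called probe sets with 1 gene and with groups that do not overlap, and 5 and 5 between the lines. Always included are the SUMO pathway genes, the promoter genes aex-3 and unc-54, and unc-119 and rol-6, common transformation markers, since the labels name none. From each list with a called member come up to 4 members with the smallest p, from each other list up to 2, and up to 3 from each class named. In tests on simulated data with the aex-3 SUMO contrast and 14204 probe sets, limma recovered 40.3% of 67 probe sets changed by 1.5-fold, 80.6% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and called 10 unchanged ones. For the same contrast, camera passed a list of 30 genes raised by 0.5 (log2) and did not pass an unchanged list. The simulated genes were drawn independently, while the estimated correlation within the real lists reached 0.763, for ribosomal proteins. The check therefore does not show that the preset correlation suits the real lists. The limma simulation changed 200 of 14204 probe sets, far fewer than were called against N2 in the data.

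Alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, a pseudocount 4 times as large (6.491) or 4 times as small (0.4057), eBayes without a trend or with robust hyperparameters, array quality weights, a fit of the compared groups only, the replicate number as a block, a minimum change of 1.5-fold, and leaving out each array. For lists they were the estimated correlation, fry, the block, the mean of all probe sets of a gene and quantile normalization. Chosen after seeing the data were the lists without N2 replicate 1, the split of the adult list, counts of list and class members under other scalings, the N2 arrays divided 1 and 2, and the tests of array scaling, RNA degradation, spike-ins, ranks of adult transcripts and smo-1 given at the end. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.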

Results

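RNA abundance was measured on 9 Caenorhabditis elegans expression arrays, each hybridised with RNA from whole animals labelled as synchronised larvae of the first stage. The arrays fall into 3 groups of 3. N2, the wild-type laboratory strain, was the control. The aex-3 SUMO and myo-4 SUMO groups were lines that express His-tagged SUMO-1, the worm's small ubiquitin-like modifier, from the promoter of aex-3, a gene of neurons, or of myo-4, another name of unc-54, a myosin heavy chain gene of body wall muscle. The 3 arrays of a group stand for 3 biological replicate populations, and the p-values measure the spread between those populations, pooled over the 3 groups. The number of arrays limits the precision of every value. Values are array signal (intensity), given as mean ± SD with n = 3 per group, and changes are log2 fold changes ± SE.

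Of 22625 probe sets, 14204 were bright enough to test. The first principal component held 61.6% of the variance between arrays and separated N2, at -39.16 to -61.8, from the transgenic lines, at 19.1 to 31.6. N2 replicate 1 stood apart on the second component, which held 11% of the variance, at 36.91 against -14.79 and -17.88 for the other N2 arrays. Across probe sets, which are not independent replicates, replicate arrays correlated at r = 0.9625 to 0.9775 in N2, 0.9868 to 0.9884 in aex-3 SUMO and 0.9857 to 0.9883 in myo-4 SUMO. Centring each array on its median, in place of the deposited scaling, moved the median log2 fold change of all probe sets from -0.037 to 0.18 for aex-3 SUMO against N2. The median moved from 0.0039 to 0.15 for myo-4 SUMO against N2 and from 0.019 to -0.052 between the lines. The mean log2 ratio of 3' to 5' control probe sets was 0.906 to 1.0 on the aex-3 SUMO arrays, 0.774 to 0.886 on the myo-4 SUMO arrays and 0.77 to 0.889 on the N2 arrays.

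Transcripts of the adult germ line and of yolk were bright on every array, although the animals were labelled as first-stage larvae. In each array the median percentile rank among all probe sets was 89.3 to 93 for the 55 sperm genes bright enough to test (83.5 to 89.9 for all 60 on the array), 90.4 to 96.4 for the 21 oocyte, eggshell and other germline genes, and 98.7 to 99.7 for the 5 yolk genes. Probe sets of the major sperm protein genes, msp, took 11 to 16 of the 100 brightest places on each array, while the 31 of them made up 0.137% of all probe sets. The median signal of the oocyte part lay at 300.3 to 513.4 on the N2 arrays, at 645.2 to 771.8 in aex-3 SUMO and at 756.2 to 828.2 in myo-4 SUMO. That of the yolk part lay at 2786 to 3752 in N2 and at 3743 to 4676 in the transgenic lines. The split of this list into parts was made after its values were seen. The 3 collagen genes of the adult cuticle that were on the array, col-19, bli-1 and bli-2, had a median percentile rank of 77.9 to 90.5.

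**Figure D1:**
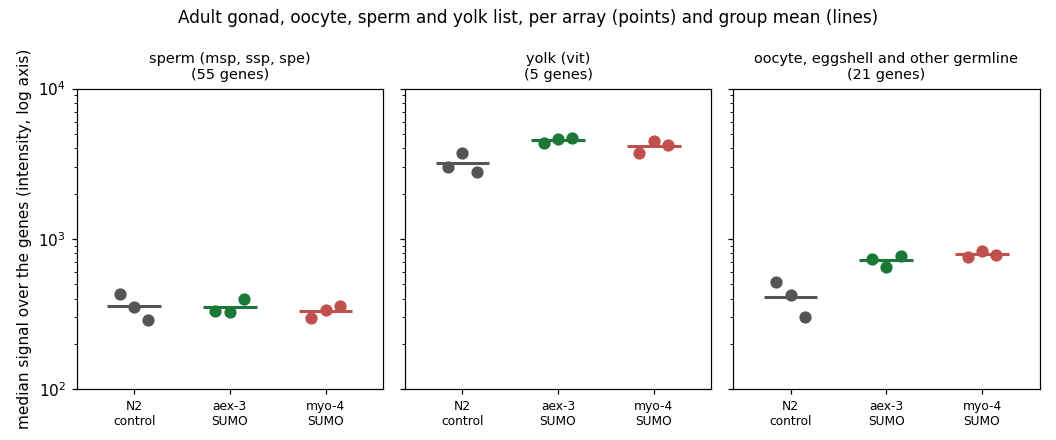
Median signal of the sperm, yolk and oocyte parts of the adult list on each array (points; array intensity, log axis) with the mean of each group (lines). The oocyte part lies at 300.3 to 513.4 on the N2 arrays and at 645.2 to 828.2 on the transgenic arrays.

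The first comparison asked how the transcriptome of animals expressing SUMO-1 from the aex-3 promoter differed from that of N2. The smo-1 transcript, which encodes SUMO, was 638 ± 110 in N2 and 1018 ± 60.1 in aex-3 SUMO, a change of 0.69 ± 0.13 (adjusted p = 0.00117), and all 3 transgenic arrays lay above the N2 arrays. Cuticle collagen genes (67 of 116), neuronal genes (36 of 66), intestinal genes (20 of 26) and histone genes (23 of 35) fell, whereas genes of ubiquitin and the proteasome (22 of 36) and of the embryo (14 of 26) rose. These lists passed camera at the preset correlation, and their calls ended with an estimated one (adjusted p = 0.204 to adjusted p = 0.290 with an estimated correlation). Among single genes, the collagen gene col-101 rose from 195 ± 127 to 1043 ± 87.9, a change of 2.63 ± 0.34 (adjusted p = 0.000105). The C-type lectin gene clec-82 fell from 249 ± 44.4 to 31.9 ± 2.42, a change of -2.89 ± 0.22 (adjusted p = 5.76e-06).

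In all, 6833 of 14204 probe sets (48.1%) passed an adjusted p of 0.05 in the limma test, 3423 higher and 3410 lower in aex-3 SUMO. Of these, 436 were at least 2-fold higher and 926 at least 2-fold lower. The median absolute change was 0.41 with a median SE of 0.16. The arrays of both groups did not overlap for 56.4% of probe sets, where chance gives 10%. The share of calls that were higher was 50.1% with the deposited scaling and 71.5% with median centring, so the balance between rises and falls depends on the scaling. Of the 10788 genes used for lists, 24.6% were called higher and 24.6% lower. Counts of list members near these shares are not particular to the list.

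The genes with the highest fold changes included C28A5.2, which rose from an N2 signal near the floor of the array (0.689 ± 0.699) to 33.5 ± 1.95, with a change of 2.48 to 5.13 over the alternatives. Changes of genes near the floor depend on the pseudocount. C17E7.9 (2.92, and 1.95 to 3.42 over the alternatives), T03D3.5 (2.82, and 1.74 to 3.48 over the alternatives), drd-10 (2.55), ing-3, a member of the inhibitor of growth family (2.51), sysm-1 (2.35), the nuclear hormone receptor gene nhr-2 (2.28, and 1.35 to 2.88), T22B7.7 (2.28, and 1.5 to 3.01) and Y45F3A.9 (2.28, and 1.40 to 2.79) rose as well. The lowest changes were those of T22F3.11 (-3.90), the C-type lectin genes clec-61 (-3.82) and clec-76 (-3.72), svct-1 (-3.72), nssp-23 (-3.18), cTel55X.1 (-3.17), C50F7.5 (-2.99), F49H6.5 (-2.70) and fmo-2 (-2.70), a flavin-containing monooxygenase gene. Their order is not fixed. Over the alternatives T22F3.11 ran from -4.51 to -3.17, clec-61 from -4.47 to -2.97, clec-76 from -4.38 to -2.83 and nssp-23 from -3.81 to -2.29. On the array scale cTel55X.1 fell from 332 ± 16 to 35.5 ± 3.54 (adjusted p = 1.26e-08). Adjusted p-values in this set ran up to 0.0029, that of T22B7.7.

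All 7 measured SUMO pathway genes rose, a count of 7 higher also when adjusted over the list alone, with a median change of 0.48. The camera test gave adjusted p = 0.00488 for the list, and adjusted p = 0.256 with an estimated correlation. They were smo-1, the SUMO protease genes ulp-5 (0.72), ulp-1 (0.67), ulp-2 (0.47) and ulp-4 (0.36), the SUMO ligase gene gei-17 (0.48) and aos-1 (0.40), which encodes a subunit of the SUMO-activating enzyme. The call of ulp-1 ended in 4 of the alternative settings. Among them were the fits without N2 replicate 3 (0.43, adjusted p = 0.115) or aex-3 SUMO replicate 1 (0.43, adjusted p = 0.140). The call of ulp-2 ended without aex-3 SUMO replicate 3 (0.42, adjusted p = 0.0510). The call of aos-1 ended without N2 replicate 3 (0.30, adjusted p = 0.0544), aex-3 SUMO replicate 1 (0.39, adjusted p = 0.0586) or replicate 3 (0.39, adjusted p = 0.0585). The call of ulp-4 ended without N2 replicate 1 (0.29, adjusted p = 0.0537), aex-3 SUMO replicate 1 (0.30, adjusted p = 0.115) or replicate 3 (0.35, adjusted p = 0.0808). Under quantile normalization 5 of the 7 rose, without gei-17 and ulp-4. Over the alternatives the adjusted p of smo-1 ran from 0.000183 to 0.00715. Oocyte, eggshell and other germline genes rose by more (16 of 21, median 0.72). The pathway's rise is not separated from theirs.

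Of 36 ubiquitin and proteasome genes, 22 rose and 0 fell in the limma test (25 rose adjusted over the list alone), with a median of 0.37 (adjusted p = 3.59e-06, and adjusted p = 0.290 with an estimated correlation). The core particle gene pas-5 rose by 0.80, and the regulatory particle genes rpt-5, rpn-5 and rpn-3 rose by 0.58, 0.57 and 0.49. Of 33 chromatin and synMuv repressor genes, which restrain vulval and germline programmes, 17 rose and 1 fell, the same counts as adjusted over the list alone, with a median of 0.43 (adjusted p = 0.000363, and adjusted p = 0.256 with an estimated correlation). Examples were lin-54 (1.03), lin-9 (0.70), dpl-1 (0.69) and lin-37 (0.67), all members of the DRM complex, which represses cell cycle and germline genes. The array held 60 genes of the embryo list, of which only 26 were bright enough to test, so the counts leave out the dim ones. Of 26 embryo genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 0.45 (adjusted p = 0.0256, and adjusted p = 0.256 with an estimated correlation). The T-box gene tbx-9 (1.47), nos-2, a Nanos homologue of the germ line (1.27), and pal-1, a caudal homologue (1.06), rose, while sdz-24 fell (-1.72). Oocyte, eggshell and other germline genes rose by more (16 of 21, median 0.72). The rises of the proteasome, chromatin and embryo lists are not separated from theirs.

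Of the 81 genes of adult gonad, oocyte, sperm and yolk, 24 rose and 7 fell (24 and 4 adjusted over the list alone). Their median of -0.0011 and mean of 0.14 differed in sign, and camera, which read them as higher, gave adjusted p = 0.170 (adjusted p = 0.714 with an estimated correlation). Under median centring 31 rose and 0 fell (median 0.22), and under quantile normalization 28 and 2 (0.15). Within the list, 16 of 21 oocyte, eggshell and other germline genes and 4 of 5 yolk genes rose, with medians of 0.72 and 0.53. The sperm genes split, with 4 of 55 higher and 6 lower at a median of -0.15, which turned to 0.07 under median centring, with 7 higher and 0 lower, and to 0.03 under quantile normalization, with 6 higher and 1 lower. Without N2 replicate 1 the median was -0.06, with 4 higher and 3 lower. The oocyte genes egg-2 (1.30), oma-2 (1.20) and rme-2, the yolk receptor (1.19), the eggshell gene perm-2 (0.85) and the yolk protein gene vit-1 (1.47) rose.

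Of 116 cuticle collagen genes, 67 fell and 7 rose (68 and 7 adjusted over the list alone), with a median of -0.65 (adjusted p = 5.99e-10, and adjusted p = 0.256 with an estimated correlation). Under quantile normalization 62 fell and 14 rose, and under median centring 57 and 12 of these collagen genes. Among them col-120 (-2.33), col-14 (-2.0), col-48 (-1.80) and rol-6 (-1.66), a collagen gene, fell. Of 68 moulting and cuticle assembly genes, 41 fell and 4 rose (42 and 4 adjusted over the list alone), with a median of -0.65 (adjusted p = 1.8e-07, and adjusted p = 0.256 with an estimated correlation). The hedgehog-related genes grd-14 (-1.35) and grl-21 (-1.34) were among those that fell. Of 26 intestinal genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.80 (adjusted p = 8.03e-07, and adjusted p = 0.256 with an estimated correlation). The cysteine protease genes cpr-4 (-1.48) and cpr-5 (-1.03) fell, as did ifd-1 (-1.26), ifb-2 (-1.17) and ifc-2 (-1.06), which encode intermediate filaments of the gut. Of 66 neuronal genes, 36 fell and 2 rose (37 and 2 adjusted over the list alone), with a median of -0.46 (adjusted p = 9.9e-07, and adjusted p = 0.256 with an estimated correlation). The neuropeptide genes nlp-12 (-1.29) and flp-7 (-1.25) fell together with sbt-1 (-0.92) and egl-21 (-0.86), which act in neuropeptide processing. The aex-3 transcript itself changed by 0.05 ± 0.63 (adjusted p = 0.957), and by -1.0 without N2 replicate 1 (adjusted p = 0.00326).

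Of 131 innate immune effector genes, 56 fell and 14 rose (58 and 14 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.000889, and adjusted p = 0.256 with an estimated correlation). Of 35 histone genes, 23 fell and 7 rose (24 and 7 adjusted over the list alone), with a median of -0.64 (adjusted p = 0.000142, and adjusted p = 0.204 with an estimated correlation). Under median centring 39 immune effector genes fell and 27 rose. The effector genes clec-54 (-1.61), spp-1 (-1.35) and irg-3 (-1.20) and the histone genes his-4 (-2.12), his-39 (-1.94), his-3 (-1.30) and his-64 (-1.12) fell. Of 46 body wall muscle genes, 14 fell and 4 rose, the same counts as adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0145, and adjusted p = 0.329 with an estimated correlation). The number that fell was 6 under median centring and 23 without N2 replicate 1. The calcium pump gene sca-1 (-0.92), the myosin genes myo-3 (-0.79) and unc-54 (-0.69 ± 0.17, adjusted p = 0.00500), mlc-3 (-0.73) and mup-2 (-0.58) fell, while unc-22, which encodes twitchin, rose (0.86). Of 74 ribosomal protein genes, 43 fell and 0 rose in the limma test (45 fell adjusted over the list alone), with a median of -0.28 (adjusted p = 9.06e-07, and adjusted p = 0.497 with an estimated correlation), but 2 fell under median centring, 3 under quantile normalization and 18 without N2 replicate 1.

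The stress lists did not pass camera. Of 10 cytosolic heat shock genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.0526, and adjusted p = 0.290 with an estimated correlation), among them the heat shock factor gene hsf-1 (0.62) and hsp-110 (0.48). Under median centring 9 heat shock genes rose and 0 fell, and under quantile normalization 7 and 0, while without N2 replicate 1 the numbers were 2 and 0 at a median of 0.30. Of 17 genes of the unfolded protein response of the endoplasmic reticulum, 0 rose and 6 fell in the limma test, as also when adjusted over the list alone. Their median of -0.07 turned to 0.15 under median centring (adjusted p = 0.281, and adjusted p = 0.375 with an estimated correlation). There 4 rose and 4 fell, against 2 and 5 under quantile normalization and 2 and 6 without N2 replicate 1. The stress sensor genes atf-6 (-0.85) and pek-1 (-0.84), the chaperone gene crt-1 (-0.65) and xbp-1 (-0.58), a transcription factor gene, fell. Of 10 genes of the mitochondrial unfolded protein response, 4 rose and 1 fell, also when adjusted over the list alone (median 0.22, adjusted p = 0.217, and adjusted p = 0.329 with an estimated correlation). Under median centring 7 rose and 1 fell, at a median of 0.44, and the median was 0.11 under quantile normalization. The mitochondrial chaperone genes hsp-60 (0.97) and hsp-6 (0.91) rose, while dve-1 (-0.93), a regulator of that response, fell. Of 21 genes of the DAF-16 and stress resistance list, 10 fell and 1 rose (10 and 2 adjusted over the list alone; median -0.25, adjusted p = 0.0558, and adjusted p = 0.262 with an estimated correlation). Under median centring 7 fell and 6 rose. Among the list's genes, dod-3 (-2.49), the metallothionein gene mtl-1 (-2.46), ttr-44 (-1.50) and dod-22 (-1.43) fell.

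The metabolic and developmental lists did not pass camera. Of 116 xenobiotic metabolism genes 28 rose and 26 fell, also when adjusted over the list alone (median 0.11, and -0.067 without N2 replicate 1; adjusted p = 0.410, and adjusted p = 0.714 with an estimated correlation), including ugt-62 (1.38) and the cytochrome P450 genes cyp-37B1 (-2.37) and cyp-34A9 (-2.17). Under median centring 43 xenobiotic genes rose and 18 fell (median 0.33), and under quantile normalization 33 and 20 (0.20). Of 74 fat metabolism and fasting genes 19 rose and 24 fell (20 and 26 adjusted over the list alone; median -0.14, and 0.08 under median centring; adjusted p = 0.355, and adjusted p = 0.550 with an estimated correlation), including ech-7 (1.82) and the desaturase gene fat-3 (-1.14). Under median centring 26 of these genes rose and 17 fell. Of 41 respiratory chain genes 5 rose and 14 fell, also when adjusted over the list alone (median -0.18, and 0.03 under median centring; adjusted p = 0.170, and adjusted p = 0.550 with an estimated correlation), including cox-11 (0.83) and ucr-2.1 (-0.67). Under median centring 10 of the respiratory chain genes rose and 1 fell, and under quantile normalization 7 and 8. Of 17 Hox and developmental transcription factor genes 3 rose and 4 fell, also when adjusted over the list alone (median -0.24, adjusted p = 0.385, and adjusted p = 0.497 with an estimated correlation). The heterochronic gene lin-42 (-1.34), lin-1 (-1.27), which acts in vulval induction, and the Hox gene mab-5 (-0.86) fell, while lin-3 (0.52), which encodes an epidermal growth factor, rose. Without N2 replicate 1, 5 of these genes rose and 6 fell at a median of -0.45, and under median centring 5 and 3 at -0.022. Of 24 pharyngeal genes 2 rose and 7 fell (2 and 5 adjusted over the list alone; median -0.33, adjusted p = 0.112, and adjusted p = 0.497 with an estimated correlation), including abu-13 (-1.0) and pha-4 (-0.79), the organ's selector gene. Under median centring 3 pharyngeal genes rose and 3 fell, and the median was -0.15 under quantile normalization.

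Median centring adds the same amount to every change in a comparison, so it weakens the lists that fell and strengthens those that rose. In aex-3 SUMO the medians became -0.43 for the collagen list, -0.44 for moulting, -0.24 for neurons, -0.42 for histones, -0.15 for immune effectors, -0.036 for muscle, -0.11 for the pharynx and -0.033 for the DAF-16 list. They became 0.59 for the list Ubiquitin and proteasome and 0.65 for the chromatin list.

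The second comparison asked the same of animals expressing SUMO-1 from the myo-4 promoter. Here smo-1 rose to 957 ± 87.5, a change of 0.59 ± 0.13 (adjusted p = 0.00318, range over the alternatives 0.000843 to 0.0176), with all 3 arrays above N2. The transcript of the promoter's own gene, unc-54, fell from 1741 ± 409 to 793 ± 147, a change of -1.12 ± 0.17 (adjusted p = 0.000267). The highest fold change was that of C38D9.2 on chromosome V, which rose from 19.5 ± 3.46 to 906 ± 32.4, a change of 5.44 ± 0.16 (adjusted p = 5.4e-10). Among the lowest were those of F49H6.5 (-5.14 ± 0.51) and ptp-4A2 (-4.53 ± 0.28), a protein tyrosine phosphatase gene that fell from 115 ± 27.1 to 3.69 ± 2.51 (adjusted p = 6.23e-07). Both ended near the floor of the array, so their size and order depend on the pseudocount, with -6.03 to -3.75 for F49H6.5 and -4.96 to -3.58 for ptp-4A2 over the alternatives. Intestinal genes (21 of 26), neuronal genes (34 of 66) and histone genes (19 of 35) fell, and genes of ubiquitin and the proteasome (26 of 36) and of the embryo (13 of 26) rose (adjusted p = 0.169 to adjusted p = 0.294 with an estimated correlation).

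The limma test called 6300 of 14204 probe sets (44.4%), 3412 higher and 2888 lower in myo-4 SUMO. At least a 2-fold change was reached by 369 of the higher and 755 of the lower ones. Groups did not overlap for 52.3% of probe sets, where chance gives 10%. The share of calls that were higher was 54.2%, and 70% with median centring. Of the 10788 genes used for lists, 24.2% were called higher and 21.1% lower, and counts of list members near these shares are not particular to the list.

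Other genes that rose most were C28A5.2 (2.30 to 4.91 over the alternatives), F08G2.5 (3.36, and 1.94 to 4.47), drd-10 (2.95), the lysozyme gene lys-10 (2.89), Y39B6A.9 (2.70), ing-3 (2.63), col-101 (2.55), C17E7.9 (2.51, and 1.62 to 2.98) and T03D3.5 (2.5, and 1.49 to 3.13), with second values over the same alternatives. Those that fell most also included svct-1 (-4.41), dod-3 (-4.15), T12D8.5 (-4.14), clec-76 (-3.90), mtl-1 (-3.89), T22F3.11 (-3.82), clec-61 (-3.80) and clec-82 (-3.50). Their order is not fixed either, with -5.01 to -3.27 for svct-1 and -4.44 to -3.12 for T22F3.11 over the alternatives. The dod-3 signal fell from 1408 ± 544 to 76.2 ± 22.4 (adjusted p = 1.49e-06). Adjusted p-values in these groups ran up to 0.00234, that of Y39B6A.9.

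Of the 7 SUMO pathway genes, 6 rose, also when adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00585, and adjusted p = 0.290 with an estimated correlation). They were smo-1, ulp-2 (0.74), ulp-5 (0.70), gei-17 (0.55), ulp-4 (0.38) and aos-1 (0.32, adjusted p = 0.0482). The call of aos-1 ended in 8 of the 9 fits that left out an array, with adjusted p up to 0.192 without myo-4 SUMO replicate 1, where the change was 0.23. It stood without N2 replicate 1 (0.41, adjusted p = 0.0118). The call of ulp-4 ended without myo-4 SUMO replicate 1 (0.37, adjusted p = 0.0681) or replicate 3 (0.33, adjusted p = 0.0822). The change of ulp-1 was 0.41 (adjusted p = 0.154), and it passed only without N2 replicate 1 (0.60, adjusted p = 0.0423). Under quantile normalization 4 of the 7 genes rose. Oocyte, eggshell and other germline genes rose by more here as well (17 of 21, median 0.78), and the pathway's rise is not separated from theirs.

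Of 36 ubiquitin and proteasome genes, 26 rose and 0 fell in the limma test (31 rose adjusted over the list alone), with a median of 0.39 (adjusted p = 1.61e-06, and adjusted p = 0.294 with an estimated correlation), among them pas-5 (0.69), rpt-5 (0.58), rpn-5 (0.57) and rpn-3 (0.52). Of 33 chromatin and synMuv repressor genes, 17 rose and 0 fell (19 rose adjusted over the list alone), with a median of 0.45 (adjusted p = 0.000146, and adjusted p = 0.290 with an estimated correlation), among them lin-54 (1.0), dpl-1 (0.80) and lin-36 (0.77). Of 26 embryo genes, 13 rose and 1 fell, also when adjusted over the list alone, with a median of 0.45 (adjusted p = 0.00773, and adjusted p = 0.290 with an estimated correlation), with nos-2 (1.16) and mex-3 (0.90) higher and sdz-24 (-1.88) lower. Of 81 adult genes 22 rose and 9 fell (22 and 5 adjusted over the list alone; adjusted p = 0.638, and adjusted p = 0.884 with an estimated correlation). Their median of -0.13 differed in sign from their mean of 0.11 and from the direction of camera. Under median centring 27 rose and 1 fell (median 0.018), and under quantile normalization 25 and 4 (0.028). The parts were 17 of 21 oocyte genes higher (median 0.78), 3 of 5 yolk genes higher (0.40; 5 and 0.65 under quantile normalization), and 2 of 55 sperm genes higher with 9 lower (-0.21), where the numbers were 3 and 3 without N2 replicate 1, 4 and 1 under median centring (-0.068) and 2 and 4 under quantile normalization (-0.027). The genes vit-1 (1.39), oma-2 (1.22), rme-2 (1.22) and egg-2 (1.20) rose. The rises of the proteasome, chromatin and embryo lists are not separated from those of the oocyte and other germline genes.

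Of 116 cuticle collagen genes, 51 fell and 7 rose (52 and 7 adjusted over the list alone), with a median of -0.40 (adjusted p = 8.29e-07, and adjusted p = 0.290 with an estimated correlation), including col-60 (-1.43), col-120 (-1.40), col-14 (-1.26) and rol-6 (-1.0). Under quantile normalization 46 fell and 15 rose, and under median centring 40 and 9 of them. Of 68 moulting and cuticle assembly genes, 28 fell and 6 rose, also when adjusted over the list alone, with a median of -0.34 (adjusted p = 0.000347, and adjusted p = 0.290 with an estimated correlation), including grl-21 (-1.16). Of 26 intestinal genes 21 fell and 2 rose, also when adjusted over the list alone, with a median of -0.86 (adjusted p = 1.51e-07, and adjusted p = 0.290 with an estimated correlation), including cpr-4 (-2.06), ifb-2 (-1.21) and cpr-5 (-1.11). Of 66 neuronal genes 34 fell and 2 rose, also when adjusted over the list alone, with a median of -0.41 (adjusted p = 8.29e-07, and adjusted p = 0.290 with an estimated correlation), including nlp-12 (-1.39), nlp-1 (-1.07), flp-7 (-1.01) and sbt-1 (-0.99). Of 35 histone genes 19 fell and 6 rose, also when adjusted over the list alone, with a median of -0.73 (adjusted p = 7.75e-05, and adjusted p = 0.169 with an estimated correlation), including his-4 (-2.33) and his-39 (-2.04). Of 131 immune effector genes 48 fell and 20 rose (51 and 20 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.00510, and adjusted p = 0.294 with an estimated correlation), including spp-1 (-1.82). Of 21 genes of the DAF-16 list 11 fell and 1 rose, also when adjusted over the list alone, with a median of -0.42 (adjusted p = 0.0173, and adjusted p = 0.290 with an estimated correlation), against 6 lower and 4 higher under median centring.

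Of 46 body wall muscle genes, where the promoter is active, 13 fell and 6 rose, also when adjusted over the list alone, with a median of -0.10 that turned to 0.04 under median centring (adjusted p = 0.222, and adjusted p = 0.591 with an estimated correlation). Under median centring 6 fell and 7 rose, while without N2 replicate 1 the median was -0.19, with 16 lower and 7 higher. The genes unc-22 (1.65) and pat-3 (0.76), a beta integrin gene of muscle attachment, rose, while sca-1 (-0.84) and myo-3 (-0.34) fell. Of 74 ribosomal protein genes 41 fell and 0 rose in the limma test (61 fell adjusted over the list alone; median -0.29, adjusted p = 3.5e-08, and adjusted p = 0.527 with an estimated correlation), but 2 fell under median centring, 2 under quantile normalization, where the median turned to 0.0017, and 14 without N2 replicate 1. Of 41 respiratory chain genes 17 fell and 5 rose, also when adjusted over the list alone (median -0.19, adjusted p = 0.0439, and adjusted p = 0.527 with an estimated correlation), against 4 lower and 7 higher under median centring and 5 and 6 under quantile normalization.

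The remaining lists did not pass camera, and where no other count is given, the count adjusted over the list alone was the same. Of 10 heat shock genes 4 rose and 2 fell (median 0.27, adjusted p = 0.243, and adjusted p = 0.527 with an estimated correlation), including hsf-1 (0.74) and hsp-12.3 (-0.88), against 6 and 1 under median centring and 5 and 1 under quantile normalization (median 0.42 in both). Of 17 genes of the unfolded protein response of the endoplasmic reticulum 3 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.735, and adjusted p = 0.810 with an estimated correlation), including atf-6 (-1.35) and pek-1 (-1.03). Their median of 0.15, which was -0.014 without N2 replicate 1 and 0.30 under median centring, differed in sign from their mean of -0.09 and from the direction of camera. Of 10 genes of the mitochondrial response 3 rose and 2 fell (median 0.18, adjusted p = 0.506, and adjusted p = 0.556 with an estimated correlation), including hsp-60 (1.01) and hsp-6 (0.90). Under median centring 5 rose and 1 fell (median 0.33), and without N2 replicate 1, 2 and 3; the median was 0.077 under quantile normalization. Of 116 xenobiotic metabolism genes 28 rose and 23 fell (median 0.06, and -0.067 without N2 replicate 1; adjusted p = 0.735, and adjusted p = 0.884 with an estimated correlation), against 36 and 22 under median centring (median 0.20) and 25 and 27 without N2 replicate 1. Of 74 fat metabolism genes 18 rose and 26 fell (median -0.15, adjusted p = 0.243, and adjusted p = 0.527 with an estimated correlation), including ech-7 (1.67) and cpt-4 (-1.80), a carnitine palmitoyltransferase gene. Under median centring 21 fat metabolism genes rose and 17 fell, at a median of -0.0061. Of 17 Hox and developmental genes 3 rose and 3 fell (median -0.10, and 0.04 under median centring; adjusted p = 0.735, and adjusted p = 0.810 with an estimated correlation), including lin-41 (0.81) and lin-1 (-0.88). Without N2 replicate 1, 4 of them rose and 5 fell at a median of -0.27, and under median centring 5 and 2. Of 24 pharyngeal genes 3 rose and 4 fell (2 and 4 adjusted over the list alone; median -0.05, 0.09 under median centring and -0.13 without N2 replicate 1; adjusted p = 0.596, and adjusted p = 0.810 with an estimated correlation). In myo-4 SUMO median centring moved the medians to -0.25 for the collagen list, -0.20 for moulting, -0.26 for neurons, -0.097 for immune effectors and -0.27 for the DAF-16 list.

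**Figure D2:**
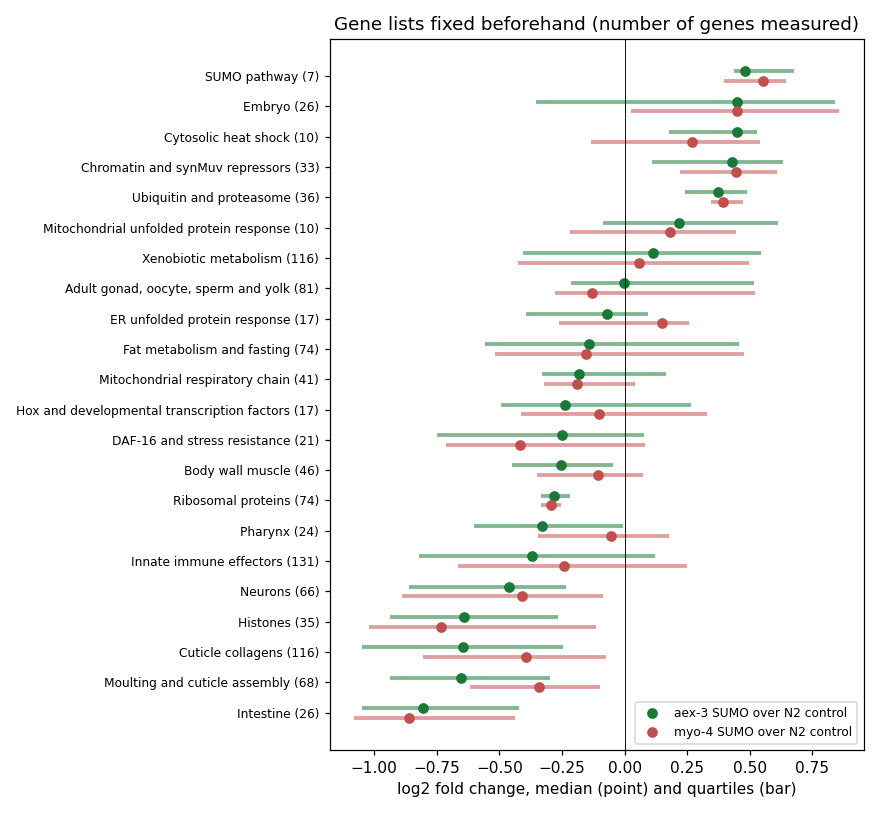
Median (point) and quartiles (bar) of the log2 fold changes of the measured genes of each list fixed beforehand, for both lines against N2. Intestinal genes lie lowest, at medians of -0.80 and -0.86, and the SUMO pathway highest, at 0.48 and 0.55, while the medians of the respiratory chain, muscle, pharynx, fat metabolism, Hox, adult and endoplasmic reticulum lists turn in at least 1 line when arrays are centred, and that of the ribosomal list turns under quantile normalization.

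The third comparison asked whether the lines, which differ in the tissue of the promoter, differed from each other, by testing myo-4 SUMO against aex-3 SUMO. With 1 line per promoter, line background or the site of insertion cannot be separated from the tissue. With the same N2 arrays in both comparisons, most of the calls against N2 were made in both lines. Of 14204 probe sets, 34 (0.239%) differed between the lines in the limma test, 26 higher and 8 lower in myo-4 SUMO, with 1247 at an unadjusted p under 0.05. C38D9.2 was 5.61 ± 0.16 higher in myo-4 SUMO (adjusted p = 3.58e-10), at 906 ± 32.4 against 17.1 ± 3.04. On the X chromosome, ptp-4A2 was lower in myo-4 SUMO by -3.95 ± 0.28 (adjusted p = 9.39e-06, and -4.37 to -3.03 over the alternatives), and cTel55X.1 was higher by 2.64 ± 0.12 (adjusted p = 4.84e-08), at 229 ± 16.3 against 35.5 ± 3.54. On chromosome V, rips-1 was 52.8 ± 13.7 in N2, 227 ± 7.69 in aex-3 SUMO and 60.9 ± 12 in myo-4 SUMO, a difference of -1.89 ± 0.18 (adjusted p = 0.000199).

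On chromosome I, K02B12.6 was 2.16 ± 0.23 higher in myo-4 SUMO (adjusted p = 0.000509). The calls of these 5 genes held under every alternative setting. W03F9.4 (2.42, adjusted p = 0.0158), the zinc finger gene ztf-13 (2.24, adjusted p = 0.0224), dod-3 (-1.66, adjusted p = 0.0320), ZC504.1 (-1.58, adjusted p = 0.0499) and clec-48 (-0.97, adjusted p = 0.0114) differed as well. Each of these lost its call without at least 1 of the aex-3 SUMO or myo-4 SUMO arrays. Without myo-4 SUMO replicate 2 the adjusted p was 0.0942 for W03F9.4, 0.178 for ztf-13, 0.234 for dod-3, 0.239 for ZC504.1 and 0.107 for clec-48. Without aex-3 SUMO replicate 1 it was 0.0784 for W03F9.4, 0.193 for dod-3, 0.312 for ZC504.1 and 0.0694 for clec-48. The call of W03F9.4 also ended without myo-4 SUMO replicate 3 (adjusted p = 0.0691), that of ztf-13 without aex-3 SUMO replicates 2 or 3 or myo-4 SUMO replicate 3 (0.0735, 0.0898 and 0.0962), that of dod-3 without aex-3 SUMO replicate 2 or myo-4 SUMO replicate 1 (0.108 and 0.148) and that of clec-48 without the same arrays (0.0509 and 0.0764). ZC504.1 lost its call without any one of the 6 arrays compared, with adjusted p-values of 0.106 to 0.312. The number called was 92 without N2 replicate 1 and 84 without N2 replicate 3. It was 505 with array quality weights, 21 without an intensity trend and 246 with only the compared groups in the fit, which leaves out the spread of N2. It was 18 without aex-3 SUMO replicate 1, without myo-4 SUMO replicate 1 or without myo-4 SUMO replicate 3, and 13 without myo-4 SUMO replicate 2. Groups did not overlap for 20.8% of probe sets, where chance gives 10%.

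**Figure D3:**
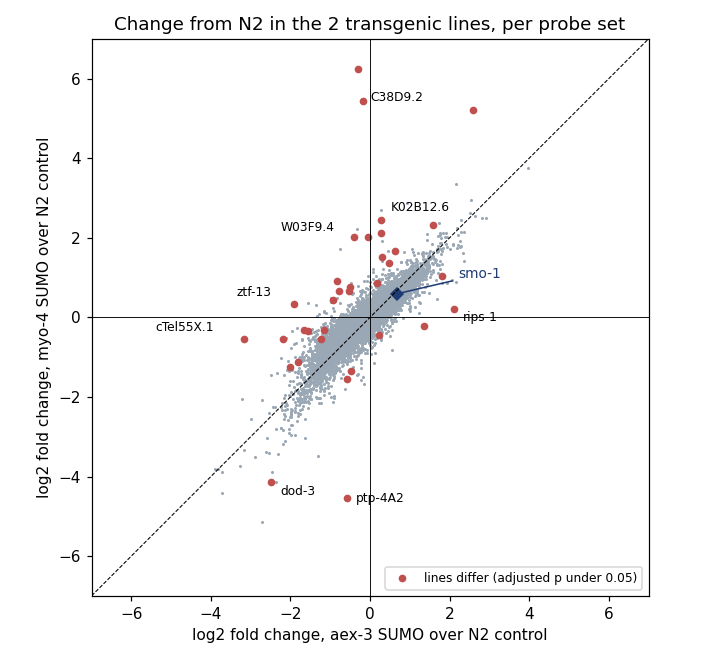
Log2 fold change against N2 of each of 14204 probe sets in aex-3 SUMO (horizontal) and myo-4 SUMO (vertical), with the 34 that differed between the lines in red and smo-1 as a diamond. Most points lie along the diagonal, while C38D9.2 and ptp-4A2 lie far from it.

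**Figure D4:**
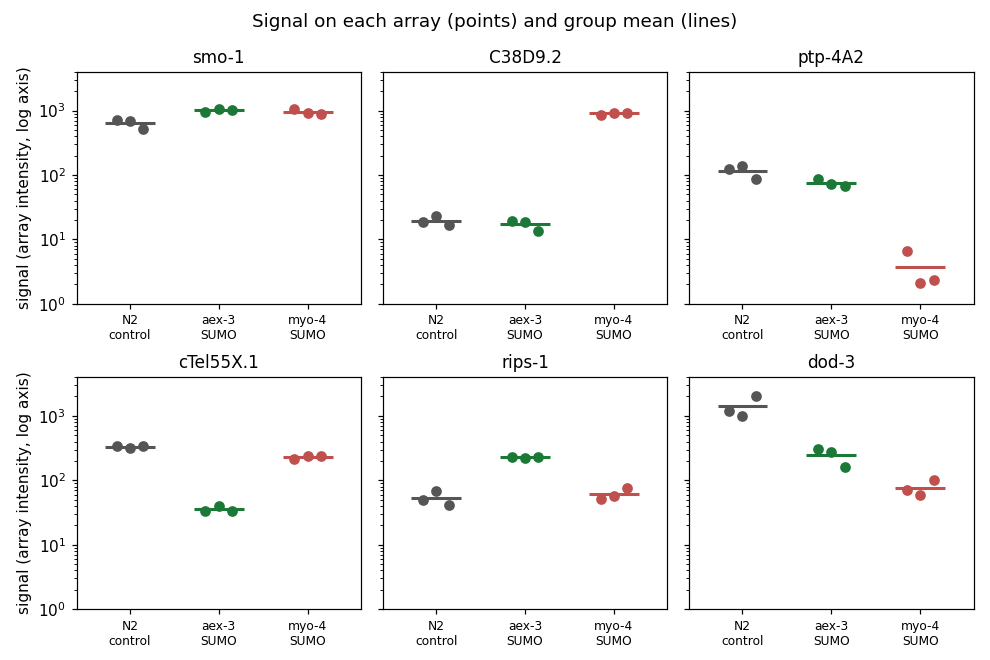
Signal of 6 genes on each of the 9 arrays (points; array intensity, log axis) with the mean of each group (lines). C38D9.2 is at 906 in myo-4 SUMO against 19.5 in N2, and cTel55X.1 is at 35.5 in aex-3 SUMO against 332 in N2.

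The smo-1 transcript did not differ detectably between the lines (-0.09 ± 0.13, adjusted p = 0.900), nor did unc-54 (-0.43 ± 0.17, adjusted p = 0.453), aex-3 (0.04 ± 0.63, adjusted p = 0.994) or rol-6 (0.65 ± 0.15, adjusted p = 0.108). The labels name no transformation marker; unc-119 and rol-6 were included as common ones. The unc-119 transcript changed by 0.41 ± 0.21 in aex-3 SUMO (adjusted p = 0.113), where it passed under quantile normalization (0.60, adjusted p = 0.0300) and median centring (0.63, adjusted p = 0.0181), and by -0.027 in myo-4 SUMO (adjusted p = 0.925), a direction that turned to 0.12 under median centring and 0.11 under quantile normalization. Against N2, aex-3 changed by 0.08 in myo-4 SUMO (adjusted p = 0.924), and by -0.96 without N2 replicate 1 (adjusted p = 0.00443).

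Of 116 collagen genes, 4 were higher in myo-4 SUMO than in aex-3 SUMO and 0 lower in the limma test (20 higher adjusted over the list alone), with a median of 0.16 (adjusted p = 2.55e-09, and adjusted p = 0.477 with an estimated correlation). They were col-130 (1.35, adjusted p = 0.0273), col-14 (0.74, adjusted p = 0.0273), dpy-8 (0.70, adjusted p = 0.0336) and col-48 (0.69, adjusted p = 0.0434). The number called was 1 under median centring, 2 under quantile normalization and 8 without N2 replicate 1. Without myo-4 SUMO replicate 2 their adjusted p-values were 0.227 for col-130, 0.234 for col-14, 0.234 for dpy-8 and 0.305 for col-48. Without aex-3 SUMO replicate 1 they were 0.193, 0.199, 0.231 and 0.279 in the same order. Without myo-4 SUMO replicate 3 they were 0.0691, 0.106, 0.122 and 0.134, and without aex-3 SUMO replicate 3 they were 0.138, 0.144, 0.0798 and 0.144. Without myo-4 SUMO replicate 1 the calls of col-130 (0.0985), dpy-8 (0.0815) and col-48 (0.0534) ended, and without aex-3 SUMO replicate 2 those of dpy-8 (0.0995) and col-48 (0.0588). Of 68 moulting and cuticle assembly genes 0 were called by limma (5 higher adjusted over the list alone), with a median of 0.25 (adjusted p = 7.55e-12, and adjusted p = 0.294 with an estimated correlation). Of 46 body wall muscle genes 0 were called by limma (5 higher adjusted over the list alone; median 0.11, adjusted p = 0.00718, and adjusted p = 0.477 with an estimated correlation). Of 24 pharyngeal genes 0 were called by limma (median 0.21, adjusted p = 0.0173, and adjusted p = 0.477 with an estimated correlation). Among 131 immune effectors, clec-174 (1.26, adjusted p = 0.00629) and irg-5 (1.21, adjusted p = 0.0196) were higher in myo-4 SUMO. Without myo-4 SUMO replicate 3 their adjusted p-values were 0.0542 and 0.0691, and that of irg-5 was 0.133 and 0.0608 without aex-3 SUMO replicates 1 and 3, and 0.0979 and 0.130 without myo-4 SUMO replicates 1 and 2. In the same list clec-48 was lower, and 5 were higher and 3 lower adjusted over the list alone. The remaining 18 lists, the immune one included, did not pass camera, with adjusted p-values of 0.141 to 0.910 (0.477 to 0.971 with an estimated correlation). Adjusted over the list alone, 2 DAF-16 genes, 2 xenobiotic genes and 1 heat shock gene were lower, 2 histone genes were higher and 1 lower, and 1 embryo gene was higher. Median and mean differed in sign for the heat shock list (0.0081 and -0.30), the xenobiotic list (0.017 and -0.015) and the ubiquitin and proteasome list (-9.17e-05 and 0.016).

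Against N2, 2834 probe sets were higher and 2484 lower in both lines, where independent calls would give 822.3 and 693.3, and 4 went in opposite directions. Both comparisons use the same N2 arrays, which that expectation leaves out, so part of the excess may come from the shared controls. In 100 simulated draws of unchanged groups against shared controls, the mean overlap was 0.02 higher and 0 lower. Such groups hold no changes to call, and only 1 draw had any probe set higher in both. An overlap near 0 was thus fixed beforehand. It cannot show how much the shared controls add to the overlap of the real calls. Across probe sets the log2 fold changes of both lines correlated at r = 0.9072. Unchanged groups would correlate too, at 0.474 on average over 100 simulated draws, between -0.773 and 0.957. The covariance was 0.351 against 0.024 in those draws, between -0.0149 and 0.126. With the N2 arrays divided 1 and 2, so that each line had its own, the 6 ways gave 1153 to 2127 probe sets higher and 1130 to 1830 lower in both lines, 6 to 73 in opposite directions, r = 0.6764 to 0.7979 and covariances of 0.295 to 0.351. A single control array makes these values imprecise, and it has no spread of its own, so the spread comes from the other arrays.

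Genes called in myo-4 SUMO against N2 were less frequent on the X chromosome, at 563 of 1464 measured genes (38.5%) against 45.4% of all genes (Fisher exact test, two-sided, adjusted p = 4.82e-08), and more frequent on chromosome I, at 904 of 1848 (48.9%, adjusted p = 0.00277). The departure of chromosome I ended at an adjusted p under 0.2 for the genes (66.2% against 64%, Fisher exact test, adjusted p = 0.0869). These counts pool rises and falls. By direction, the median change of X genes was -0.33 in aex-3 SUMO and -0.24 in myo-4 SUMO, against 0.020 and 0.047 on the autosomes. No chromosome departed in the pooled count of aex-3 SUMO against N2, where the lowest adjusted p was 0.357 on the X, with 47.1% against 49.4%, or between the lines, where the lowest was 0.228. At an adjusted p under 0.2 chromosomes I and III held fewer (adjusted p = 0.00838 and adjusted p = 0.0434) and V more (adjusted p = 0.0298) of the genes that differed between the lines. Genes whose nearest measured neighbour was called in the same direction numbered 1918 in aex-3 SUMO against a mean of 1307 in 10000 random draws, and 1639 against 1111 in myo-4 SUMO (permutation p = 1e-04 for both, the smallest the draws can give). Of the 30 genes placed on a chromosome that differed between the lines, 0 had such a neighbour (permutation p = 1, random mean 0.0534), but at an adjusted p under 0.2 for the genes 7 of 159 did (permutation p = 0.007, random mean 1.387).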

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

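The tests of smo-1 in this part were chosen only after its result was seen. The differences from N2 were unlike between the lines for 34 of 14204 probe sets, by the limma test of the difference itself, against 505 with array quality weights and 246 with only the compared groups in the fit. The differences below are myo-4 SUMO minus aex-3 SUMO on the log2 scale, with 3 arrays in each group. They were 5.61 for C38D9.2, 2.64 for cTel55X.1, 2.42 for W03F9.4, 2.24 for ztf-13, 2.16 for K02B12.6, -3.95 for ptp-4A2, -1.89 for rips-1, -1.66 for dod-3, -1.58 for ZC504.1 and -0.97 for clec-48. Among list members they were 1.26 for clec-174, 1.21 for irg-5, 1.35 for col-130, 0.74 for col-14, 0.70 for dpy-8 and 0.69 for col-48. Other splits of the 6 arrays called 0 probe sets at most against the real 34. The real split was 1 of 10, so the share cannot go under 0.1. Those splits mix arrays of both lines within a group, so real differences widen their spread and keep their calls few.

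The smo-1 transcript was higher in both lines and did not differ detectably between them. A technical explanation was not tested, since no probe sequence was at hand to show which part of the construct the probe set detects. If the transgene's own transcript were the source, smo-1 could be expected to rise beyond the other SUMO pathway genes. The excess was 0.12 (0.123; exact permutation p = 0.214 over 84 splits of the arrays), which leaves that open. A shift shared with the pathway is a candidate explanation too, since 6 of the 6 other members were higher in at least 1 line. Their mean changes were 0.517 in aex-3 SUMO and 0.518 in myo-4 SUMO, near that of smo-1. Such a shift need not be particular to the pathway. The oocyte, eggshell and other germline genes rose by more (16 and 17 of 21, medians 0.72 and 0.78), and the pathway's rise is not separated from theirs. Among all genes the change of smo-1 lay at percentiles 90.1 and 86.8. The transgene's contribution and the shared shift cannot be told apart, because it is unknown whether the smo-1 probe set reads the transgene.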

How the results depend on the processing

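The counts of list members without N2 replicate 1 and under median centring, the class counts under scaling alternatives and the split of the adult list were chosen only after the results were seen. The numbers of probe sets called against N2 stayed within 1.5 times of 6833 and 6300 under every alternative except a minimum change of 1.5-fold, which by its construction calls fewer: 4309 for aex-3 SUMO and 3767 for myo-4 SUMO. Leaving out each array gave 5214 to 7376 and 4779 to 6849. The replicate number as a block gave 6464 and 5971, and 36 between the lines, of which 27 were called in the main fit. The number that differed between the lines, 34, was 21 without an intensity trend and 505 with array quality weights. It was 246 with only the compared groups in the fit and 13 to 92 when each array was left out. The main fit pools the spread over the groups, so that of N2 enters this contrast, which holds no N2 array. N2 replicates were further apart, with SDs of log2 differences of 0.388 to 0.51 against 0.287 to 0.314 in the lines. The count of 34 thus rests on a spread wider than that of the lines compared. The cause of the other moves was not tested. The correlation of both fold changes was 0.835 with no filter on dim probe sets; the cause was not tested. With an estimated correlation, 0 lists passed camera in each comparison and 0 classes, against 12, 13 and 4 lists and 53, 50 and 17 classes with the preset one; fry called 20, 17 and 0 lists, since it asks another question. At an adjusted p under 0.2 in place of 0.05 for the genes, the number of chromosomes that departed went from 2 to 1, without chromosome I, in myo-4 SUMO against N2 and from 0 to 3 between the lines; the cause was not tested. Named results numbered 286, and the stricter filter on dim probe sets covered only 245 of them. With that gap, over 21 settings 5715 kept their direction and side of the threshold, 176 lost the call, 49 gained it and 25 reversed. For 66 list results and 6 settings these numbers were 335, 37, 18 and 6. There the direction is that of camera or fry, and median centring is not among the settings, so medians turned in further cases.

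Directions reversed for values near 0 or with a wide spread, and the cause was not tested. For aex-3 in aex-3 SUMO against N2 the change was -0.12 with the larger pseudocount, -0.58 with array quality weights and -1.0 to 0.61 when each array was left out. In myo-4 SUMO against N2 it was -0.085, -0.50 and -0.96 to 0.65. Between the lines aex-3 was at -0.050 under quantile normalization, -0.033 under median centring and -0.056 to 0.20 when each array was left out. For unc-119 in myo-4 SUMO against N2 these were 0.11, 0.12 and -0.26 to 0.12. Between the lines ulp-4 was at -0.052 under median centring, -0.035 with array quality weights and -0.062 to 0.089 when each array was left out, gei-17 at -5.14e-05 under median centring and -0.022 to 0.13, and ulp-5 at -0.068 to 0.022. Median changes of lists that reversed against N2 included -0.067 for xenobiotic metabolism in aex-3 SUMO and -0.0666 in myo-4 SUMO without N2 replicate 1, and in myo-4 SUMO -0.014 for the endoplasmic reticulum list without N2 replicate 1 and 0.099 for the pharynx, 0.0017 for ribosomal proteins and 0.028 for the adult list under quantile normalization. For the adult list in aex-3 SUMO it was 0.15 under quantile normalization and 0.081 without N2 replicate 1. Those under median centring against N2 stand with the lists. Between the lines they included -0.0072 for the list Ubiquitin and proteasome with the mean of a gene's probe sets, 0.0040 for ribosomal proteins, -0.0068 for neurons, -0.049 for xenobiotic metabolism and 0.0035 for the intestine under quantile normalization, and -0.020 for the SUMO pathway, whose direction in fry differs. Under median centring they were -0.063 for heat shock, -0.031 for immune effectors, -0.049 for chromatin, -0.020 for the embryo, -0.022 for neurons and -0.054 for xenobiotic metabolism. The deposited table holds no detection calls, so signal over background was not tested; genes near the floor, such as C28A5.2, have changes that depend on the pseudocount.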

Other observations

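Tests of array scaling, RNA degradation, spike-ins and the ranks of adult transcripts and adult collagens in this part were chosen only after the results were seen; the test of the X chromosome and the splits of the arrays were not. Beyond the lists, several classes of genes named by a shared symbol passed camera at the preset correlation in both lines, and 0 of 147 classes passed with an estimated one. Of 25 nucleoporin genes (npp), which build the nuclear pore, 22 rose in aex-3 SUMO and 23 in myo-4 SUMO, with medians of 0.62 and 0.65 (adjusted p = 0.370 and adjusted p = 0.401 with an estimated correlation). Examples are npp-2 (0.82 and 0.76), npp-3 (0.75 and 0.85) and npp-5 (0.93 and 0.80). All 8 genes of SR splicing factors (rsp) rose in both lines, with medians of 0.68 and 0.77 (adjusted p = 0.390 and adjusted p = 0.401 with an estimated correlation), among them rsp-1 (0.87 and 0.71) and rsp-4 (0.81 and 0.85). Of 12 prp genes, which act in splicing, 10 and 9 rose, and of 8 mcm genes, which act in DNA replication, 6 and 7 rose (adjusted p = 0.370 and 0.401 for prp, adjusted p = 0.394 and 0.475 for mcm, with an estimated correlation). Under quantile normalization 6 and 5 prp genes rose. Of 33 mrpl genes of the mitochondrial ribosome, 17 and 15 rose (adjusted p = 0.376 and 0.426 with an estimated correlation), and 26 and 23 under median centring. The oocyte, eggshell and other germline genes rose by as much in the same lines (16 and 17 of 21, medians 0.72 and 0.78), so the rises of these classes are not separated from those of germline transcripts.

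Of 120 nuclear hormone receptor genes (nhr), 52 fell and 6 rose in aex-3 SUMO, and 60 fell and 7 rose in myo-4 SUMO, with medians of -0.45 and -0.49 (adjusted p = 0.394 and adjusted p = 0.401 with an estimated correlation). Among them nhr-88 was at -1.87 and -1.82, and nhr-134 at -1.34 and -1.23. Of 17 math genes, 11 fell in aex-3 SUMO and 13 in myo-4 SUMO, where 1 rose, with math-38 at -1.98 and -2.70 (adjusted p = 0.394 and adjusted p = 0.401 with an estimated correlation). Of 10 bus genes, named for mutants whose surface changes the interaction with bacteria, 10 and 9 fell, with medians of -1.18 and -0.70 (adjusted p = 0.370 and adjusted p = 0.401 with an estimated correlation). Between the lines the bus genes had a median of 0.53 (adjusted p = 1.19e-05, and adjusted p = 0.538 with an estimated correlation), with 0 of 10 called by limma and 5 higher adjusted over the class alone. These directions were the same under quantile normalization, median centring and without N2 replicate 1.

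Transcripts of sperm, oocytes and yolk were bright on all 9 arrays of animals labelled as first-stage larvae. Cross-hybridisation within the msp family alone is argued against by the adult-list members outside it, whose median percentile rank was 80.2 or more on every array, and by the oocyte and yolk parts, at 90.4 and 98.7 or more. Material from animals at or near adulthood in every population is a candidate explanation, since 3 collagen genes of the adult cuticle, which are not germline genes, had a median rank of 77.9 or more on every array, dim probe sets included. Ranks compare different probe sets within an array, without a detection call, which limits both arguments, and 3 genes give weak support. How such material came into the populations, as adults left after bleaching or as a later stage than labelled, was not tested and stays open.

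Near 1 in 2 probe sets differed from N2 in each line, with 6833 and 6300 calls. Other splits of the arrays gave a highest of 0. The real split was 1 of 10 in each comparison, so the share cannot go under 0.1. Those splits mix N2 and transgenic arrays within a group, so the difference itself widens their spread and keeps their calls few. Their 0 therefore does not show what chance would call. Array scaling as the whole cause is argued against by quantile normalization, which kept at least 80.7% of the calls with their sign. RNA degradation in myo-4 SUMO is argued against by a 3' to 5' difference from N2 of -0.00276 (log2, exact permutation p = 0.9). In aex-3 SUMO the difference was 0.108 (exact permutation p = 0.1, the smallest 3 against 3 arrays can give), beside a median absolute change of 0.405. The 2834 higher and 2484 lower calls that aex-3 SUMO shared with myo-4 SUMO argue against degradation for those probe sets, since myo-4 SUMO had no such shift. For the other calls of aex-3 SUMO degradation may account for part. The spike-ins gave no sign of a separate hybridisation of the N2 arrays, since their variance lay with the replicate number (86.4%) and not with the group (4.13%). They cannot exclude it, because a separate hybridisation of equal efficiency need not shift them. A larger share of germline transcripts in both lines may account for part. Genes higher in both lay on the X, where germline genes are rare, less often than genes lower in both (84 of 2197 against 404 of 1951, odds ratio 0.152, Fisher exact p = 3.62e-67). That ratio depends on the falls of X genes too, while 3.82% of the genes higher in both and 13.6% of all measured genes lay on the X. Within the adult list, the oocyte, eggshell and other germline genes rose (16 and 17 of 21). Yolk genes rose too (4 and 3 of 5), but they are counted apart from the germline genes and do not bear on that share. Of 55 sperm genes, 4 rose and 6 fell in aex-3 SUMO, and 2 and 9 in myo-4 SUMO, under the deposited scaling. Culture and RNA preparation, which the labels do not date, the age of the animals and SUMO-1 itself stay open, as untested.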
